A study of Rattus norvegicus with 2 samples.

How the data were processed

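The assay was ChIP-seq, in which DNA crosslinked to a protein is recovered with an antibody and sequenced. Per the labels' protocols, 40000000 INS1 832/13 cells were fixed with 4% formaldehyde for 10 min. Chromatin was cut with 3000 or 5000 gel units of micrococcal nuclease and then sonicated. It was immunoprecipitated with 2.5 µg of an anti-DBP antibody, and libraries were read from both ends over 51 bp. The labels give 2 groups with 1 library each, DBP ChIP and input DNA. The processed data used here were the authors' peak list for the DBP library; no signal, count or peak file of the input library was used.

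The submitters' processing notes name HISAT2 2.1.0 (a read aligner), MACS2 2.2.7 (a peak caller), HOMER 4.11.1 (a motif and annotation suite) and the rat build rn6. How each was run, the peak threshold, the treatment of duplicate reads and the use of the input as control are not given in the sources used here. The deposited list gives chromosome, start, end and a numbered name for each peak, and no score, fold enrichment, p or q value, summit or read count. The peak set therefore reflects a threshold that cannot be varied here, peaks cannot be ranked by strength, and depth, copy number and mappability, which all affect where peaks are called, could not be corrected for. Starts were converted to count from 1. The running numbers in the names reach 2240. Of these, 6 numbers, 2199 to 2204, between the last peak of chromosome 9 and the first of chromosome X, have no line, and these were not analysed here.

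Before the data were examined, tests were fixed for the D-box core motif and a panel of other motifs in peaks, for the share of peaks in promoters, for gene lists near peaks (core clock, insulin secretion and exocytosis, beta-cell transcription factors, mitochondrial metabolism, unfolded protein response, PAR bZIP targets, markers of other cell types, ribosomal proteins and histones) and for the authors' peak statistic by motif and by promoter. None of these 6 results was computed. The first 4 need the sequence or gene annotation of rn6, which was not used here, and the last 2 need a peak statistic. For the same reason the rule for named genes, which took the nearest genes of the highest peaks and list members with a peak within 10 kb, named none, and no peak is assigned to a gene. A gene table of another assembly, GRCr8, was at hand and was not used, since coordinates of different builds cannot be mixed.

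The description of the list (number, width and chromosome of the peaks) was planned, and the tests of density, windows, gaps and widths were chosen after the list was seen. Density was the number of peaks divided by the distance from the first base to the end of the last peak of each chromosome. Each chromosome's mean count per whole 5 Mb bin was compared with that of all other bins by drawing as many bins at random 100000 times (two-sided, Benjamini-Hochberg adjustment over 21 chromosomes, threshold 0.05). Bins rather than peaks were permuted because neighbouring peaks are not independent. This does not remove dependence between neighbouring bins, so the p-values may be too small. Dense windows were windows of 1 Mb starting at a peak whose number of peak midpoints exceeded the genome-wide maximum of 95% of 1000 random placements with the same number of peaks per chromosome, and overlapping windows were reduced to the densest. The same number of placements, with peak widths kept, gave the random counts of close neighbours and the longest stretch without a peak. These tests were one-sided, for counts or lengths as large as those observed. Random placement takes no account of gene density, mappability, assembly gaps or copy number. Widths were compared by the difference in medians with 100000 permutations of single peaks, which ignores that neighbouring peaks are not independent; grouped and isolated peaks were therefore compared again with 1 peak per group (of each chain with gaps under 100 kb, the first peak whose nearest neighbour was 500 bp or more away, which left out 42 of 311 chains that held no such peak) and 20000 permutations within chromosomes. Peaks are regions of 1 library and not replicates, so p-values describe this list. Alternatives joined nearby peaks, kept only wider peaks, changed bin and window sizes, left out chromosome 1, used an exact binomial test of counts or placed peaks within 5 Mb bins.

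The tests were checked, with fewer draws and placements, on 20 random lists of 2234 peaks on average. They were also checked on 20 such lists in which 1 chromosome was then raised to 2-fold density and 5 windows of 12 peaks were added. The raised chromosome was called in all 20 lists and all 100 added windows were found. Of the random lists, 0 had a chromosome called and 1 had a window called. Positions in these lists were independent, whereas the real peaks are grouped, so the rate of false calls among grouped peaks was not measured. The 12 added peaks also exceed the 9 that a window of the real list needed, so recovery near that threshold was not checked. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.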

Results

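Chromatin occupancy of DBP was examined in INS1 832/13 cells, a glucose-responsive clone of a rat insulinoma line that serves as a model of the pancreatic beta cell. DBP (D-site albumin promoter binding protein) is a PAR bZIP transcription factor whose abundance oscillates with the circadian clock. The series held 2 libraries, 1 from chromatin immunoprecipitated with an anti-DBP antibody and 1 of input DNA. The question set by the design was where DBP is bound in these cells. The values analysed were the positions of the peaks called for the DBP library. There were no replicates, so no value below has a replicate error, and no test between the DBP and input libraries was made. The read depth of either library is unknown from the peak list, and the peaks carried no score, fold enrichment, summit or q value. Intervals are 95% intervals. Those on counts, shares and densities cover counting error only, and those on differences in median width come from resampling peaks. Both kinds treat peaks as independent, so they may be too narrow where peaks are grouped. The tests compare positions or widths within this 1 list.

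The DBP library yielded 2234 peaks on all 20 autosomes and on chromosome X of the rn6 assembly. They covered 495153 bp in total. The median width was 193 bp, with quartiles of 139 and 267 bp and a mean of 222 ± 114 bp (SD over peaks). No peak was narrower than 109 bp, and 100 peaks had exactly this width, which was 4.48% of the list (exact Clopper-Pearson interval 3.66 to 5.42%). The next most frequent width, 113 bp, was held by 26 peaks. Only 76 peaks, or 3.40%, were wider than 500 bp. The widest peak spanned 1115 bp on chromosome 1 (82108133 to 82109247). It was followed by a peak of 986 bp on chromosome 7 (11164248 to 11165233), one of 932 bp on chromosome 5 (64030695 to 64031626) and one of 881 bp on chromosome 7 (60474236 to 60475116). These were chosen by rank after their values were seen, and the genes at these positions were not analysed here.

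**Figure D1:**
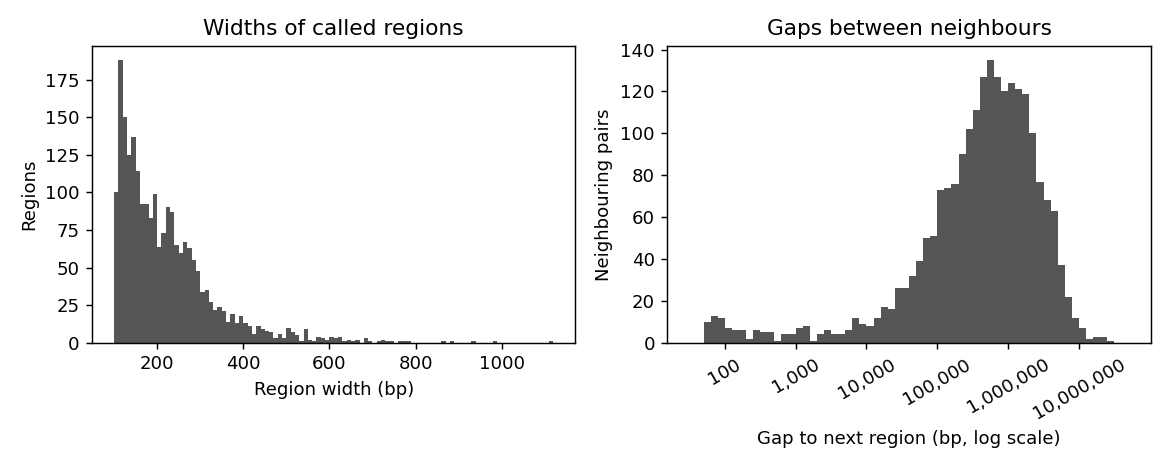
Left, number of called DBP peaks by width in bp, in bins of 10 bp. Right, number of neighbouring peak pairs by the gap between them in bp, on a log scale. Widths start at 109 bp, and a small group of pairs lies under 500 bp, apart from the main distribution. The median gap over all pairs is 530 kb.

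DBP peaks were unevenly spread over the chromosomes. Peaks were densest on chromosome 10, with 159 peaks and 1.41 peaks per Mb (exact Poisson interval 1.20 to 1.65). Chromosome 12 followed with 71 peaks and 1.36 per Mb (1.06 to 1.72), then chromosome 1 with 343 peaks and 1.23 per Mb (1.11 to 1.37) and chromosome 7 with 175 peaks and 1.20 per Mb (1.03 to 1.40). Peaks were sparsest on chromosome X, with 36 peaks and 0.264 per Mb (0.185 to 0.366), and on chromosome 15, with 31 peaks and 0.279 per Mb (0.190 to 0.396). Chromosome 1 alone held 15.35% of all peaks, whereas chromosomes X and 15 held 1.61% and 1.39%. Lengths were counted to the last peak of each chromosome, 2726 Mb in all with a mean of 0.820 peaks per Mb, so each density is an upper estimate for the whole chromosome.

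Each chromosome was compared with all others by its mean count per 5 Mb bin, in a two-sided permutation test of the bins with Benjamini-Hochberg adjustment over 21 chromosomes. Chromosome 1 exceeded the others by 1.62-fold (6.18 against 3.82 peaks per bin, permutation adjusted p = 0.00021), chromosome 10 by 1.82-fold (7.14 against 3.93, permutation adjusted p = 0.004) and chromosome 7 by 1.51-fold (5.97 against 3.95, permutation adjusted p = 0.023). Chromosome X carried 0.290 times the count of the others (1.22 against 4.21, permutation adjusted p = 0.002), chromosome 15 carried 0.327 times (1.36 against 4.18, permutation adjusted p = 0.0075) and chromosome 8 carried 0.547 times (2.27 against 4.15, permutation adjusted p = 0.038). The other 15 chromosomes did not pass the threshold. Chromosome 12 was above the others in 5 of 9 alternative settings and chromosome 9 below in 3 of 9. In the main setting, chromosome 12 stood at 1.70 times the others (permutation adjusted p = 0.065) and chromosomes 6 and 9 at 0.641 and 0.589 times (permutation adjusted p = 0.076 for both). The calls on chromosomes 7 and 8 were lost when 10 Mb bins were used (1.34 and 0.551 times the others, permutation adjusted p = 0.2 and 0.1) and when bins began at the first peak (1.44 and 0.590 times, permutation adjusted p = 0.06 and 0.067), and that on chromosome 8 also without chromosome 1 (0.581 times, permutation adjusted p = 0.053).

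**Figure D2:**
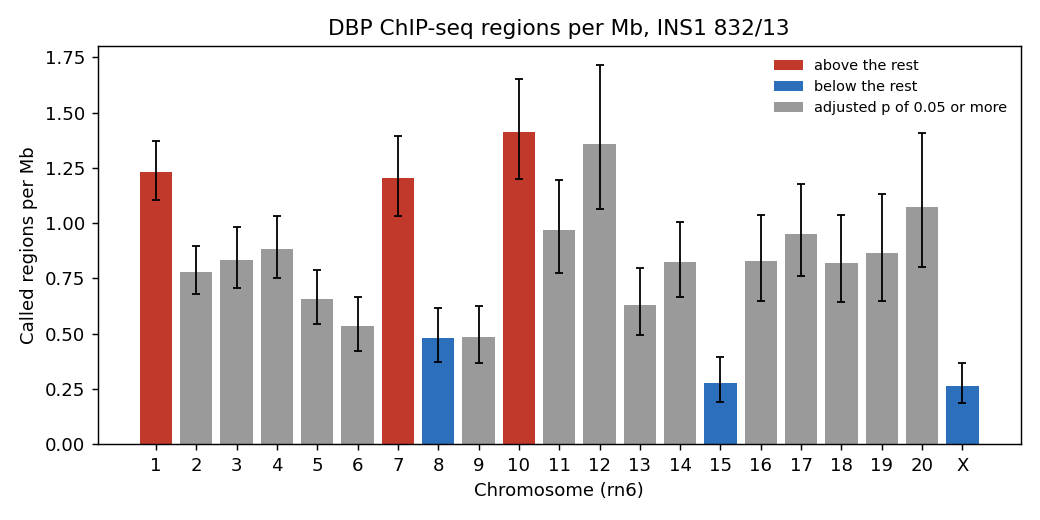
DBP peaks per Mb on each rn6 chromosome. Bars give the peak count divided by the length up to the last peak, error bars the 95% exact Poisson interval, and colours the outcome of the permutation test of 5 Mb bins. The interval treats peaks as independent and may be too narrow for grouped peaks. Chromosomes 1, 7 and 10 lie above the rest, and chromosomes 8, 15 and X below.

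Along the chromosomes, DBP peaks formed local groups. Of 2213 pairs of neighbouring peaks, 419 (18.9%) lay under 100 kb apart, 2.12 times the 198 ± 12.7 (SD) pairs found in 1000 random placements of the same peaks on their own chromosomes. At under 10 kb there were 142 pairs against 21.2 ± 4.56 at random, and at under 500 bp 72 pairs against 1.57 ± 1.26. With peaks within 500 bp joined, the pairs under 10 kb numbered 70 against 19.8 ± 4.49, so that the ratio to random fell from 6.70 to 3.54, and those under 100 kb 347 against 185 ± 12.5, a ratio of 1.88. Each count had a permutation p of 0.001, the smallest value that 1000 placements can give. When peaks were moved only inside their own 5 Mb bin, which keeps regional density, the count under 100 kb was still 1.63 times the random mean of 256 ± 13.8 pairs (permutation p = 0.001). That count includes the 72 pairs under 500 bp, and joining was not combined with placement inside bins. The variance of the count per 5 Mb bin was 3.25 times its mean, against a mean of 1.54 and at most 1.76 in 200 random placements of the peaks on their own chromosomes, and 55 of 534 bins (10.3%) held no peak.

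In 5 windows of 1 Mb the number of peaks reached 9 or more, a size reached anywhere in the genome in fewer than 5% of random placements. Together they held 57 peaks, or 2.55% of the list. They were picked for their high counts, which the Poisson interval and the multiples of chromosome means below do not allow for. The densest lay on chromosome 1 from 100889740 to 101885253, with 18 peaks in 996 kb (exact Poisson interval 10.7 to 28.5), which is 14.6 times the chromosome's mean. Its genome-wide permutation p was 0.001, and no random placement held more than 10 peaks in 1 Mb. A second group on chromosome 1, from 80207995 to 81152727, held 12 peaks, 9.73 times the chromosome's mean (genome-wide permutation p = 0.001). Groups of 9 peaks each lay on chromosome 3 from 164120527 to 164985744, on chromosome 7 from 140728292 to 141530416 and on chromosome 12 from 7151201 to 7881443, at 10.8, 7.48 and 6.62 times their chromosomes' means (genome-wide permutation p = 0.039 for each). With peaks up to 10 kb apart joined, the windows on chromosomes 1 and 3 still passed, with 13, 11 and 9 joined peaks, and those on chromosomes 7 and 12 did not, with 6 and 7. The window on chromosome 3 was lost with windows of 0.5 Mb and among peaks wider than the median.

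The longest stretch without a peak spanned 31.3 Mb of chromosome 3, from 24675918 to 55951519. A stretch as long arose somewhere in the genome in few random placements (permutation p = 0.005). The placements treat peaks as independent, whereas grouped peaks leave longer empty stretches, so this p-value may be too small. The next stretches, 23.1 Mb on chromosome 5 (78384426 to 101526431), 21.5 Mb on chromosome 13 (3805503 to 25257841) and 21.2 Mb on chromosome X (83698297 to 104855745), did not pass the same test (permutation p = 0.075, 0.12 and 0.13). That test used the longest stretch on any chromosome, each at its own density. Sparse chromosomes such as X and 15 therefore weighed on every p-value. No stretch was compared with placements of its own chromosome alone. Whether the stretches on chromosomes 3, 5 and 13 are long for the density of their own chromosome was thus not tested.

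**Figure D3:**
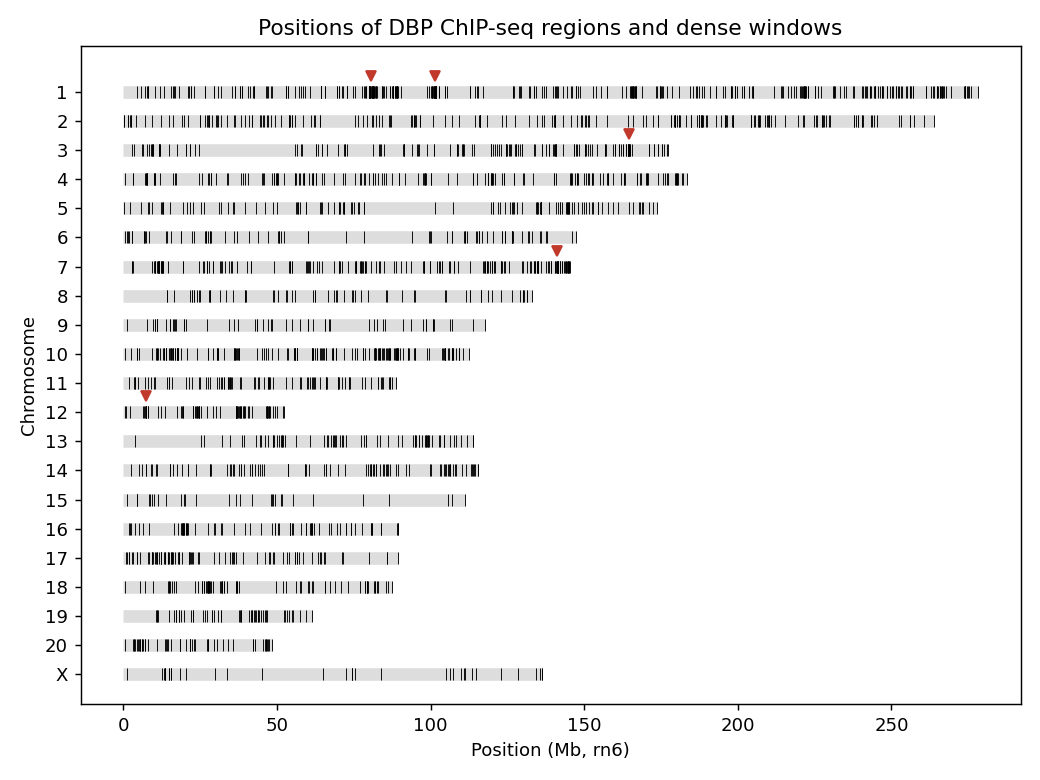
Positions of the 2234 DBP peaks on the rn6 chromosomes, in Mb. Black ticks are peaks, grey bars reach to the last peak of each chromosome, and red triangles mark the 5 dense windows of 1 Mb, 2 of them on chromosome 1. The stretch of 31.3 Mb without a peak is seen on chromosome 3.

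Grouped peaks had a larger median width than isolated peaks, but the difference passed only in the test that treats peaks as independent. The 591 peaks whose nearest neighbour lay between 500 bp and 100 kb away had a median width of 211 bp, against 187.5 bp for the 1504 peaks with no neighbour within 100 kb. The difference of 23.5 bp (bootstrap interval 7.0 to 37.0) passed a two-sided permutation test of single peaks (adjusted p = 0.0006 over 5 width comparisons). That test ignores the dependence of neighbouring peaks. With 1 peak taken from each of the 269 groups that held a peak with its nearest neighbour 500 bp or more away, and widths permuted within chromosomes, the difference was 15.5 bp (bootstrap interval 0.5 to 35.5) and did not pass (permutation p = 0.061). Peaks within the 5 dense windows had a median of 219 bp against 192 bp elsewhere, a difference of 27.0 bp (interval -3.0 to 63.0) that did not pass (permutation adjusted p = 0.35). The 36 peaks on chromosome X had a median of 171 bp and the 31 on chromosome 15 one of 198 bp, and their differences from the other chromosomes, -22.0 bp (interval -52.5 to 13.0) and 5.0 bp (interval -46.0 to 51.0), did not pass (permutation adjusted p = 0.49 and 0.82).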

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

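Every alternative except joining peaks within 500 bp and keeping assembled chromosomes, both for the number of peaks, was chosen after seeing the data. The number of peaks was 2162, 2092 and 1815 with peaks within 500 bp, 10 kb and 100 kb joined. It was 2234 on assembled chromosomes, which was fixed in advance, since every listed peak lay on one. Chromosomes 10, 15 and X kept their calls in 8 of 8 alternatives with a density ratio (1.60 to 1.95, 0.326 to 0.390 and 0.245 to 0.308 times the others), and chromosome 1 in 7 of 7 (1.43 to 1.80). Chromosome 7 kept its call in 6 of 8 (1.34 to 1.79) and chromosome 8 in 5 of 8 (0.423 to 0.607). The number of chromosomes below the others rose from 3 to 5 with 2 Mb bins and to 7 with the exact binomial test of counts, which treats neighbouring peaks as independent, and the number above rose from 3 to 4 in both, as chromosome 12 was added. Chromosome 12 was called above in 5 of 9 alternatives, and chromosome 9 below in 3 and chromosome 6 in 2 of 9. The 5 dense windows became 3 with peaks within 500 bp or 10 kb joined, 3 without chromosome 1, which holds the other 2, 6 with 0.5 Mb windows and 8 with 2 Mb windows. Among peaks wider than the median there were again 5, but without those on chromosomes 3 and 12 and with others on chromosome 1 (220966505 to 221894082) and chromosome 10 (55685343 to 56629928). A window overlapping each of the 2 on chromosome 1 was found in 5 of 6 alternatives, the one on chromosome 3 in 4 of 7, on chromosome 7 in 4 of 7 and on chromosome 12 in 2 of 7. With peaks within 100 kb joined there were 0, which the joining nearly fixes. The excess of pairs under 100 kb stayed between 1.60 and 2.76 times random (permutation p = 0.001 in each of 5 alternatives). The greater width of grouped peaks fell from 23.5 to 15.5 bp with 1 peak per group permuted within chromosomes and no longer passed (permutation p = 0.061). The planned stricter threshold could not be run without a peak statistic, nor could the planned motif, promoter and gene list alternatives without rn6 sequence or annotation. Read depth is unknown, so a chromosome or stretch with few peaks may hold sites below the unknown threshold. No paired analysis was possible because each group has 1 library.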

Other observations

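The test below of width on chromosomes 15 and X and the relation of width to density were chosen after the values were seen. Across 21 chromosomes, those with more DBP peaks per Mb also had wider peaks: Pearson's r was 0.540 (permutation p = 0.011) and Spearman's rho 0.574 (permutation p = 0.0075), and without chromosomes 10 and X r was 0.495 (p = 0.031). This was the only relation of its kind computed, and chromosomes are not independent replicates. Median widths ran from 169 bp on chromosome 8 to 222 bp on chromosome 19. Groups of 3 peaks with gaps under 500 bp occurred at 5 places, namely on chromosome X from 74261314 to 74262518, chromosome 10 from 17693194 to 17694357, chromosome 3 from 91195810 to 91196941, chromosome 9 from 10801139 to 10802103 and chromosome 14 from 53683953 to 53684865.

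Chromosomes 15 and X had 0.279 and 0.264 peaks per Mb, although only one of them is a sex chromosome. If their peaks were only less grouped, the deficit would vanish when peaks within 100 kb are counted once. Instead, 2 of the 2 chromosomes stayed below the others, at 0.390 (chromosome 15) and 0.293 times (X), against 0.327 and 0.290 unjoined. That outcome was nearly fixed, since joining only took the list from 2234 to 1815 peaks, too small a drop to close such a deficit. Grouping under 100 kb was thus too limited in this list to account for the deficit, and wider grouping was not tested. A second candidate explanation is weaker signal over the whole chromosome, from lower copy number in this cell line, which would leave narrower peaks. The median width on the 2 chromosomes, set against the rest, differed by -14.0 bp (interval -43.0 to 16.0, permutation p = 0.4). Taken singly, they went opposite ways, by -22.0 bp on X (interval -52.5 to 13.0) and by 5.0 bp on 15 (interval -46.0 to 51.0). With intervals this wide, weaker signal stays open for both. Gene content and mappability were not tested, copy number was examined only through peak width, and the design gives no group for a biological explanation.

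The dense windows may in principle arise from one broad enriched stretch cut into several peaks. After joining peaks up to 10 kb apart, 3 of the 5 windows still passed. For the windows on chromosomes 1 and 3, this argues against a cut into pieces up to 10 kb apart. Those on chromosomes 7 and 12, which held exactly the 9 peaks needed, fell to 6 and 7 stretches and no longer passed, and their excess stays open. With joining up to 100 kb, the windows on chromosomes 1 and 3 held only 4, 5 and 5 stretches. Joining that wide nearly fixes such a drop, so a cut into pieces more than 10 kb apart stays open. Locally raised read depth from amplified DNA would widen peaks. The pooled difference of 27.0 bp (interval -3.0 to 63.0) cannot decide, and it joins unlike windows. The median width was 282.5 bp in the densest window and 217.5 bp in the other on chromosome 1. It was 175.0, 220.0 and 202.0 bp in those on chromosomes 3, 7 and 12, against 192 bp outside the windows. No window was tested alone. A high local density of genes is a biological explanation that was not tested.

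The 72 pairs under 500 bp apart may largely be single enriched stretches split by the caller's joining rule. Of these gaps, 66.7% were under 150 bp (48 of 72, exact interval 54.6 to 77.3%), the median was 106.5 bp and the smallest was 54 bp, just above the read length of 51 bp. The pile-up of peaks at exactly 109 bp is likewise consistent with a minimum width set in peak calling, a setting that is not given in the sources used here. Counting each such stretch once gives 2162 peaks and leaves the chromosome calls as they were. Whether the gaps also follow the spacing of nucleosomes, which micrococcal nuclease spares, was not tested.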
